A study of Mus musculus with 7 samples.

How the data were processed

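RNA was measured in CD24 and CD29 positive cells sorted from femurs of LFD and HFD mice. Per the labels' protocols, RNA was extracted from lysed cells with a column kit, copied with a low-input SMART-Seq kit, made into libraries with Nextera XT and sequenced as paired-end reads. The deposited values are counts per Ensembl gene, whole numbers that the authors did not normalize, with 1 column per library. The submitters' processing notes name bcl2fastq 2.20, cutadapt, STAR 2.5.2b, HTSeq 0.11.2, DESeq2 1.26.0 and the mm10 build, with no order or settings. The strand setting, the handling of reads that map to several places and the annotation release are not given in the sources used here. Overlapping genes and near-identical copies such as Bglap and Bglap2 or the globin genes are therefore uncertain, since their reads may have been shared or dropped. The kits amplify by PCR without molecular identifiers, so intervals and floors cover counting error only.

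The table held 42687 gene identifiers, of which 42250 had a symbol in the reference name table and 437 did not. Counts of identifiers with no symbol made up 0.0138% to 0.0216% of a library and stayed in the totals. Coordinates came from a GENCODE annotation of the same build. No member of the mitochondrial genome list was in the table used, and that list is not analysed here. Libraries were grouped by the diet in their titles. No pair of libraries agreed within sampling noise (chi-square per degree of freedom from 57.3 to 670.5), so none looked like 1 library sequenced again. Separately amplified libraries of 1 sample could also differ by more than that noise, so this does not show separate samples. Each library was kept as 1 sample. Nothing in the labels says that the libraries came from separate animals, and p-values measure the spread between these samples, which may be technical in part.

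The diets were compared with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with TMM normalization, filterByExpr by group, robust fitting and diet as the sole term, and Benjamini-Hochberg adjustment at 0.05. This left 14304 genes with a common biological coefficient of variation of 0.628. Fold changes are HFD against LFD. Gene lists were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, two-sided, with adjustment over the biology lists and over the cell type lists separately, for lists with at least 5 tested members. The 27 biology lists and 15 cell type lists were fixed before the data were examined, as were the test, the list of alternatives and the rule for named genes. Camera with an estimated correlation and fry were alternatives. The share of counts in each cell type list was compared by an exact permutation test of the difference between group means of log2(percent + 0.001) over the 35 assignments of 7 libraries into 4 and 3, two-sided, whose smallest p is 0.0286.

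The rule for named genes took, per direction, up to 12 genes with the largest change among those past the threshold, with a mean of at least 8 CPM and groups that did not overlap, filled up to 6 with the smallest unadjusted p. It left out cell type markers, the sex-linked genes Xist, Ddx3y, Kdm5d, Uty and Eif2s3y, and ribosomal, mitochondrial, receptor segment and unnamed genes. It kept other X-linked genes, and Drp2, Timp1 and Tsc22d3, named below, lie on X. It added 2 to 4 members of each biology list with the smallest p, 2 members of each cell type list with the highest CPM, the sorting and lineage genes Cd24a, Itgb1, Ptprc and Pecam1, and the 5 genes with the highest CPM. Within that rule, 4 members were kept for lists past the camera threshold and 2 for others, a choice made after the data were seen. Other genes named for having passed when adjusted over the list alone, and the X-linked genes that escape inactivation, were also chosen after their values were seen. For genes with 0 counts in a group, folds were computed against a floor of 3 counts over the group. Of the listed genes 2 of the B lineage, 1 monocyte and 1 endothelial gene had a group at 0, and setting them to that bound left the medians at 0.72, 1.59 and -1.26.

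The edgeR procedure was tested on simulated counts with the real means, depths and spread and 200 changed genes. With the spread of each gene as estimated, it recovered 4% of genes changed by log2 1, 62% of those changed by 2 and 90% of those changed by 3 for this comparison, over 13575 genes, with 3 false calls. Simulated genes were drawn independently of each other, and the changed ones had a mean of at least 8 CPM. Real genes moved together in some lists, so recovery and false calls may differ in the real data. Alternatives were RLE and upper-quartile normalization, no filter beyond 1 count, a stricter filter of 10 counts in 4 libraries, fitting without robust estimates, an adjusted p under 0.1, each library left out, replicate number as a block, 1 surrogate variable (sva 3.50.0), DESeq2 1.42.0 and limma-voom with quality weights. The median log2 fold change of all genes was 0.02 with TMM, 0.00 with RLE and 0.04 with upper-quartile scaling.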

Results

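Transcripts were measured in cells that carried both CD24 and CD29 (integrin beta 1, the product of Itgb1) on their surface and were sorted by flow cytometry from digested mouse femurs. The labels name this population skeletal stem cells of bone. C57BL/6 mice that were 3 months old at the start ate food with 10% fat (the low fat diet, LFD) or with 60% fat (the high fat diet, HFD) over 4 weeks, and the comparison asks which transcripts in the sorted cells differed between the diets. There were 4 LFD libraries (numbers 1 to 4) and 3 HFD libraries (numbers 2 to 4). Total counts per library ranged from 17391613 to 24681838, and 15394 to 18850 genes had at least 1 count. Values below are CPM, counts relative to the TMM-scaled library total, as mean ± SD with n = 4 for LFD and n = 3 for HFD, and coordinates are those of the mm10 build.

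The most abundant transcripts belonged to cartilage, bone and red cells. Col2a1, the main cartilage collagen, measured 22454 ± 8855 CPM in LFD and 29737 ± 8844 CPM in HFD, and Col1a1, the main bone collagen, 13208 ± 8458 and 20791 ± 5995 CPM. Sparc (osteonectin) measured 13667 ± 1250 and 23185 ± 3536 CPM. The beta globin gene Hbb-bs reached 55792 ± 9023 CPM in LFD and 31745 ± 21350 CPM in HFD, and the alpha globin gene Hba-a1 21310 ± 6233 and 10274 ± 5727 CPM. None of these 5 genes passed the adjusted threshold of edgeR's quasi-likelihood test, Sparc was called by DESeq2, and the sign of Col2a1 turned with limma-voom (log2 fold change 0.41 in the main test and -0.07 with limma-voom).

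Diet and sex-linked transcripts separated the libraries in the same way. Xist, the RNA that coats the inactive X chromosome, had 257 to 526 counts in each LFD library and 0 counts in each HFD library, and was at least 486-fold lower in HFD when 3 counts over the group, relative to its TMM-scaled total, were taken as the floor. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y together had 1 to 5 counts in each LFD library and 2494 to 3405 counts in each HFD library. Eif2s3y was at least 598-fold higher and Kdm5d at least 162-fold higher in HFD by the same floor, and the ratio of HFD to LFD was 959 for Ddx3y (95% counting interval 441 to 2616) and 416 for Uty (162 to 1529). The labels give no sex. All 4 LFD libraries thus had the transcripts of female animals and all 3 HFD libraries those of male animals, so every difference between the diets below is also a difference between these sexes. Of 5 X-linked genes that escape inactivation, chosen after the data were seen, none passed edgeR's adjusted threshold, and the log2 fold changes were -1.21 for Kdm6a (adjusted p = 0.450), -0.77 for Kdm5c, -0.76 for Eif2s3x, -0.39 for Pbdc1 and -0.14 for Ddx3x, with Kdm6a and Eif2s3x at an unadjusted p under 0.05.

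**Figure D1:**
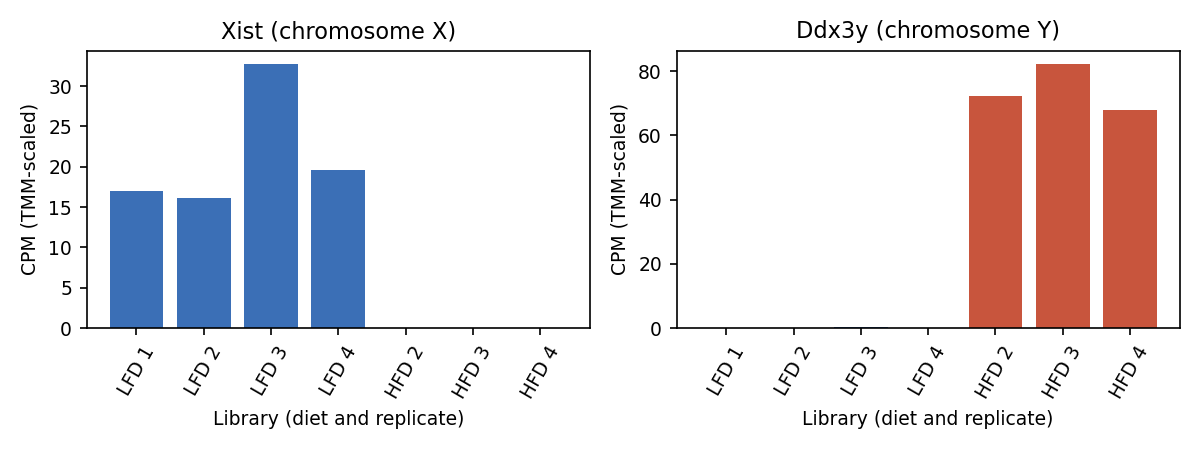
TMM-scaled CPM of Xist and of Ddx3y in each library, with LFD libraries in blue and HFD libraries in red. Xist was between 16.1 and 32.7 CPM in the 4 LFD libraries and 0 in the 3 HFD libraries, and Ddx3y was between 67.8 and 82.3 CPM in the HFD libraries and at most 0.187 CPM in the LFD libraries.

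Of 14304 genes tested with edgeR, 5 passed an adjusted p of 0.05, 4 higher and 1 lower in HFD. Ddx3y, Uty and Eif2s3y rose and Xist fell, and the remaining gene was C5ar1, the receptor for complement fragment C5a found on neutrophils and macrophages. C5ar1 (ENSMUSG00000049130, chromosome 7, 16246743 to 16259540) rose from 16.3 ± 5.14 to 93.4 ± 7.14 CPM, a log2 fold change of 2.52 ± 0.26 (SE, adjusted p = 0.0304). It kept its direction under every alternative run, with adjusted p between 1.12e-14 and 0.480, and did not pass after any single library other than LFD 4 was left out (adjusted p from 0.0834 to 0.279, and 0.0290 without LFD 4). Its call also rested on the sex-linked genes ranked beside it, since with Xist and the 4 Y-linked genes left out of the adjustment C5ar1 had an adjusted p of 0.138 and edgeR called 0 genes, with 1072 at an unadjusted p under 0.05. An unadjusted p under 0.05 was seen for 1077 genes (741 higher and 336 lower in HFD), where evenly spread p-values would give 715. Of the 34 other splits of the libraries 4 gave more such genes (up to 2391) and the median was 256, so that chance was not excluded for this number. The groups did not overlap for 1698 genes (11.9%, where chance gives 5.71% on average over splits). Genes can move together and such genes were not counted in the other splits, so chance was not excluded for this number either. The number of genes called depended strongly on the tool, with 28 genes by limma-voom with sample quality weights and 361 genes by DESeq2, and all 5 edgeR genes were among both sets.

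The genes next in order under the rule for named genes did not pass edgeR's adjusted threshold of 0.05. That rule required groups that did not overlap, so their separation is not a result. Notch3 came in as a member of a biology list, without that condition, and its groups did not overlap either. Igfbp4, a binding protein for insulin-like growth factors (chromosome 11, 99041244 to 99054392), measured 57.2 ± 20.3 CPM in LFD and 310.2 ± 47.0 CPM in HFD (log2 fold change 2.44 ± 0.31, adjusted p = 0.0830). Slc2a3, a glucose transporter, had a log2 fold change of 2.51 ± 0.31. Plaur, the urokinase receptor, had 2.30 ± 0.29, and Mgst1, a microsomal glutathione transferase, 1.43 ± 0.19. Agt (angiotensinogen) measured 29.1 ± 4.57 CPM in LFD and 90.1 ± 21.6 CPM in HFD (log2 fold change 1.63, adjusted p = 0.1099). Among genes with lower values in HFD, the receptor Notch3 (chromosome 17, 32120820 to 32166852) measured 112 ± 10.8 and 37.8 ± 7.89 CPM (log2 fold change -1.57 ± 0.21, adjusted p = 0.0830). The alcohol dehydrogenase Adh1 measured 16.9 ± 5.41 and 4.21 ± 0.486 CPM. Adh1, Lmbr1 (-1.90), the X-linked gene Drp2 (-1.77), Tshz3 (-1.75) and the receptor Fgfr4 (-1.28) had adjusted p from 0.217 to 0.232. DESeq2 called each of the genes of this paragraph.

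**Figure D2:**
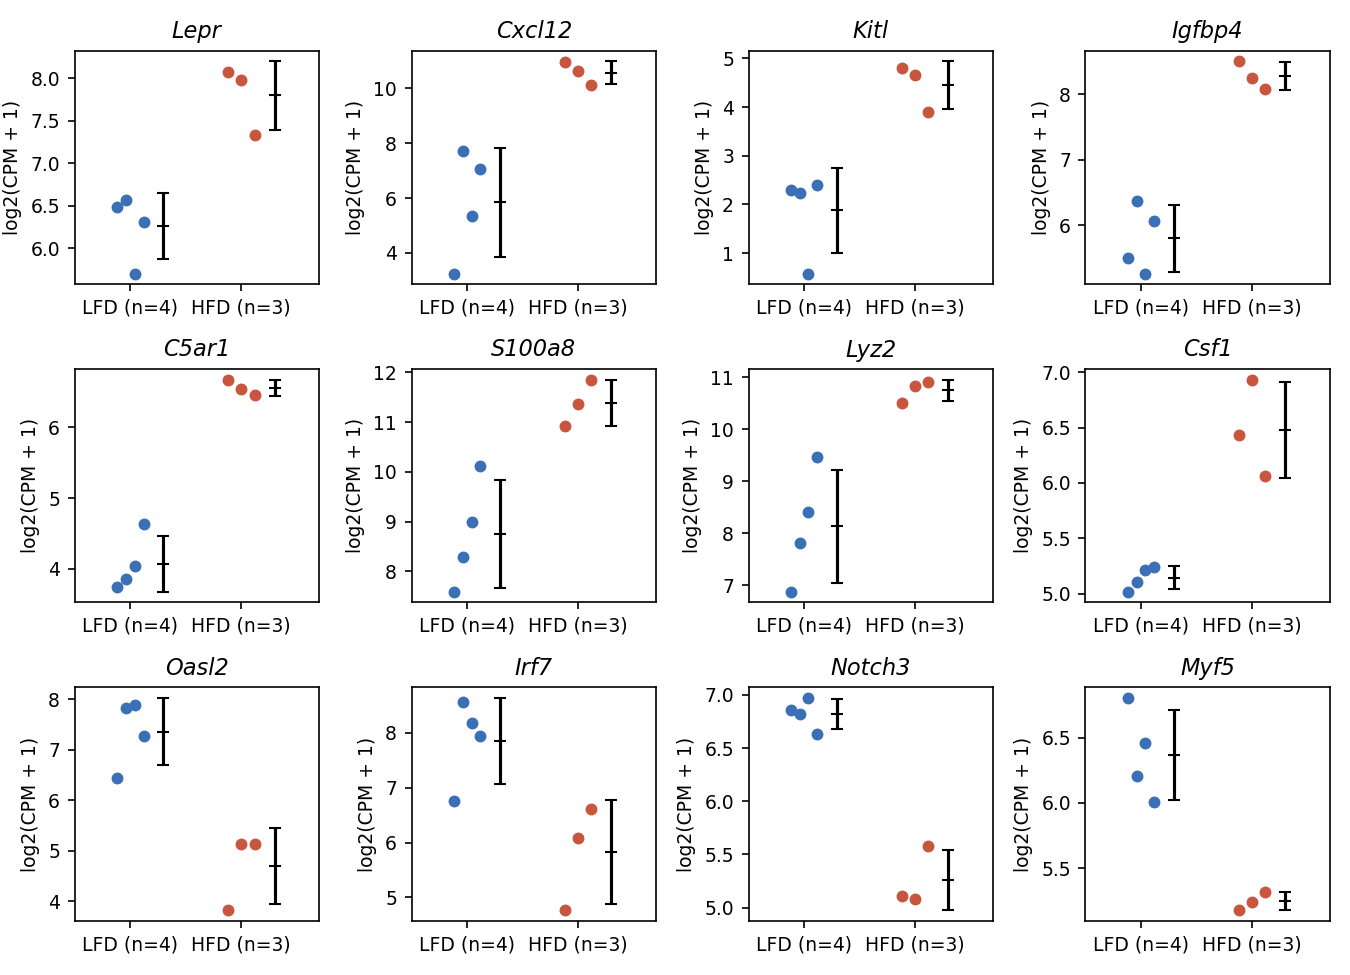
Values of 12 named genes as log2(CPM + 1), with 1 point per library and the mean and SD of each group beside the points. The 3 HFD libraries did not overlap the 4 LFD libraries for any of these genes, of which C5ar1 alone passed edgeR's adjusted threshold. Other named genes, such as Omd, Bglap and Il1b, had groups that overlapped and are not shown.

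Stem and stromal progenitor genes were higher in HFD as a group. Of 23 tested members 17 were higher and 6 lower, with a median log2 fold change of 0.81, and the list rose by camera (adjusted p = 0.00320 with a preset correlation, adjusted p = 0.670 with an estimated correlation). Lepr, the leptin receptor and a marker of marrow stromal cells (chromosome 4, 101717404 to 101815352), measured 77.8 ± 19.0 CPM in LFD and 227 ± 58.3 CPM in HFD. Cxcl12, the chemokine that retains blood progenitors in marrow (chromosome 6, 117168535 to 117181367), measured 97.2 ± 90.4 and 1556 ± 434 CPM. The stem cell factor gene Kitl (log2 fold change 2.80 ± 0.65) and Pdgfrb (1.54 ± 0.34) also had higher values. Adjusted over the list alone 6 members passed, and over all genes tested 0 passed, with 9 at an unadjusted p under 0.05 and 4 called by DESeq2. The mean of these genes followed the share of counts in the erythroid list across the 7 libraries (Pearson r = -0.85, exact permutation p = 0.000595, and r = -0.73 within the diets, exact permutation p = 0.125), and the list did not pass once that share was in the model (adjusted p = 0.323).

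Bone and matrix genes were also higher in HFD as groups. Of 22 osteoblast genes 20 were higher (median 0.71), among them the osteocalcin genes Bglap (279 ± 106 and 674 ± 317 CPM) and Bglap2 (log2 fold change 1.22), neighbours of near-identical sequence whose reads may have been split between them, and Omd (1.33). HFD 4 lay within the LFD range for Bglap (326 CPM, LFD 141 to 392), Bglap2 (121 CPM, LFD 59.7 to 183) and Omd (174 CPM, LFD 170 to 205). The osteoblast list rose by camera (adjusted p = 0.00105, adjusted p = 0.670 with an estimated correlation), with 0 members passing when adjusted over the list alone. Of 36 extracellular matrix genes 28 were higher (median 0.47), and the list rose (adjusted p = 0.00320, adjusted p = 0.670 with an estimated correlation). The X-linked gene Timp1, for an inhibitor of matrix proteases, had a log2 fold change of 1.01 ± 0.21 and was the member that passed when adjusted over the list alone. Tenascin C (Tnc) had 1.48, Col5a2 0.71 and Loxl1 -0.79. Of 21 chondrocyte genes 17 were higher (median 0.41), with Acan at 0.70, Hapln1 at 0.82 and Sox6 at -0.98, and the list rose (adjusted p = 0.0203, adjusted p = 0.670 with an estimated correlation). No chondrocyte gene and 1 osteoblast gene (Sparc) were called by DESeq2. The chondrocyte call ended in 4 of the 7 fits that left out a library, those without LFD 1, LFD 3, HFD 2 or HFD 4 (adjusted p = 0.0579, 0.230, 0.205 and 0.101).

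Endoplasmic reticulum stress genes gave 21 higher of 22 tested, with a median log2 fold change of 0.43. Creld2 (1.08 ± 0.24), Sdf2l1 (1.09 ± 0.32), Hyou1 (1.07 ± 0.29) and Manf (0.73 ± 0.19), which encode folding factors of that compartment, passed when adjusted over the list alone, and 0 passed over all genes tested, with 9 at an unadjusted p under 0.05 and 4 called by DESeq2. The list rose by camera (adjusted p = 0.000157, adjusted p = 0.670 with an estimated correlation). Glucocorticoid targets also rose, with 12 of 14 higher, a median of 0.59 and 3 members passing when adjusted over the list alone (adjusted p = 0.00126, adjusted p = 0.670 with an estimated correlation). These were Fkbp5 (1.35 ± 0.28), the X-linked gene Tsc22d3 (1.10 ± 0.27) and Lcn2 (1.99 ± 0.53), the last of which is also on the granulocyte list.

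Cytokine and glycolysis genes had higher values in HFD. Of 23 NF-kB and cytokine genes 18 were higher (median 0.52), and the list rose by camera (adjusted p = 0.00320, adjusted p = 0.670 with an estimated correlation). Neutrophils and monocytes also express Il1b and Cxcl2, and the granulocyte list had a median log2 fold change of 2.24 in the same comparison. Csf1, the growth factor of macrophages, measured 34.5 ± 2.56 CPM in LFD and 91.0 ± 28.02 CPM in HFD and was the member that passed when adjusted over the list alone. Cxcl2 (log2 fold change 4.27 ± 1.22) and Il1b (2.76 ± 0.95) had larger changes with larger errors, and Ccl2 measured 1.41 ± 1.56 and 7.95 ± 1.38 CPM. Of 19 glycolysis genes 17 were higher (median 0.44), with Gpi1 at 0.93 and the lactate transporter Slc16a3 at 1.06, and the list rose (adjusted p = 0.00617, adjusted p = 0.670 with an estimated correlation). Immediate early and dissociation stress genes, which handling and digestion of tissue also induce, rose with 24 of 26 higher and a median of 0.33 (adjusted p = 0.00856, adjusted p = 0.710 with an estimated correlation). Antigen presentation genes rose with 12 of 16 higher and a median of 0.63 (adjusted p = 0.0258, adjusted p = 0.670 with an estimated correlation), and H2-K1 had a log2 fold change of 1.02 ± 0.28. The immediate early call ended without LFD 2 or LFD 4 (adjusted p = 0.0814 and 0.0652), and the antigen presentation call without LFD 1 or HFD 4 (adjusted p = 0.386 and 0.0821).

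Interferon response genes were lower in HFD. Of 33 tested 25 were lower (median -0.91), and the list fell by camera (adjusted p = 0.00336, adjusted p = 0.670 with an estimated correlation). Oasl2 (chromosome 5, 114896936 to 114912234) measured 175 ± 69.6 CPM in LFD and 27.2 ± 12.1 CPM in HFD (log2 fold change -2.69 ± 0.48), and Irf7, a transcription factor of the interferon response, 254 ± 112 and 63.3 ± 35.2 CPM. Psmb8, a subunit of the immunoproteasome, went the other way (1.86 ± 0.41), and Oasl2 and Psmb8 passed when adjusted over the list alone. The list's median was 0.08 with 1 surrogate variable (adjusted p = 0.943) and -0.02 with the erythroid share in the model (adjusted p = 0.537).

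Proliferation genes were lower in HFD in all 36 of 36 cases, with a median log2 fold change of -0.69 and 0 at an unadjusted p under 0.05. The groups overlapped, since the mean log2 CPM of the list was 6.57 in LFD 1, 7.24 in HFD 3 and 7.61 in HFD 4. Of the HFD libraries, HFD 2 alone (5.84) lay below every LFD library. Rrm2 measured 1844 ± 659 CPM in LFD and 982 ± 539 CPM in HFD, and Aurkb had a log2 fold change of -1.03 ± 0.54. The list fell by camera with a preset correlation (adjusted p = 5.97e-07), but its genes moved nearly as 1 (estimated correlation 0.951), and it did not pass once this was taken into account (adjusted p = 0.670 with an estimated correlation). The nuclear genes of oxidative phosphorylation fell with 60 of 75 lower and a median of -0.17 (adjusted p = 0.000157, adjusted p = 0.670 with an estimated correlation). Ribosomal protein genes fell with 68 of 78 lower and a median of -0.17 (adjusted p = 0.000806, adjusted p = 0.721 with an estimated correlation), and their call ended without LFD 1 (adjusted p = 0.202).

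The list calls depended on how hidden variation was treated. With the erythroid share in the model, an alternative chosen after seeing the data, ER stress, glucocorticoid, osteoblast, antigen presentation and ribosomal genes were still called by camera at the preset correlation (adjusted p from 0.00382 to 0.0308), and fatty acid synthesis (median -0.33, adjusted p = 0.0308) and Notch genes (-0.31, adjusted p = 0.0406) were newly called lower. The proliferation list then had a positive median (0.23, adjusted p = 0.0566), and the oxidative phosphorylation (adjusted p = 0.259), NF-kB (0.136), matrix (0.0788), glycolysis (0.323), immediate early (0.268) and chondrocyte (0.515) lists did not pass. With 1 surrogate variable the proliferation (adjusted p = 0.122), progenitor (0.126), glycolysis (0.430), immediate early (0.876) and chondrocyte (0.383) lists did not pass, and cholesterol synthesis (median -0.23, adjusted p = 0.0460) and Notch genes (-0.27, adjusted p = 0.0384) were newly called lower.

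Of the 26 biology lists tested, the remaining 12 did not pass. They included those closest to dietary fat. Of 21 fatty acid oxidation genes 10 were higher and 11 lower (median -0.05, adjusted p = 0.588), although the mean (0.20) and the camera direction were positive, and Angptl4, a target of PPAR receptors, had a log2 fold change of 1.93 ± 0.62. Of 20 fatty acid synthesis genes 12 were higher (median 0.10, adjusted p = 0.758), and of 24 cholesterol synthesis genes 16 were higher (median 0.09, adjusted p = 0.758), while the means and camera directions of both lists were negative and each was called lower under 1 of the models for hidden variation above. Of 19 adipocyte genes 11 were higher (median 0.33, adjusted p = 0.188), and Agt, Lpl and Dgat2 passed when adjusted over the list alone. Of 24 insulin and IGF pathway genes 12 were higher (median 0.10, adjusted p = 0.612), of 26 Wnt genes 19 (median 0.26, adjusted p = 0.138), of 27 BMP and TGF-beta genes 18 (median 0.20, adjusted p = 0.360), and of 18 clock genes 13 (median 0.49, adjusted p = 0.103). Of 13 Notch pathway genes 9 were lower (median -0.35, adjusted p = 0.102), with Notch3 passing when adjusted over the list alone. Antioxidant genes (8 of 21 higher, median -0.07 but mean 0.07, adjusted p = 0.598), p53 targets (12 of 22, median 0.06, adjusted p = 0.742) and lysosome genes (11 of 22, median 0.06, adjusted p = 0.758) completed the set, and for the p53 and lysosome lists the camera direction was negative. Calls appeared when single libraries were left out, for clock genes without LFD 1 or HFD 4 (adjusted p = 0.0221 and 0.0213), Notch genes without LFD 2 or HFD 2 (0.0457 and 0.0361) and Wnt genes without HFD 4 (0.0251). Igfbp4 and the cystine transporter gene Slc7a11 passed when adjusted over the insulin and antioxidant lists alone.

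**Figure D3:**
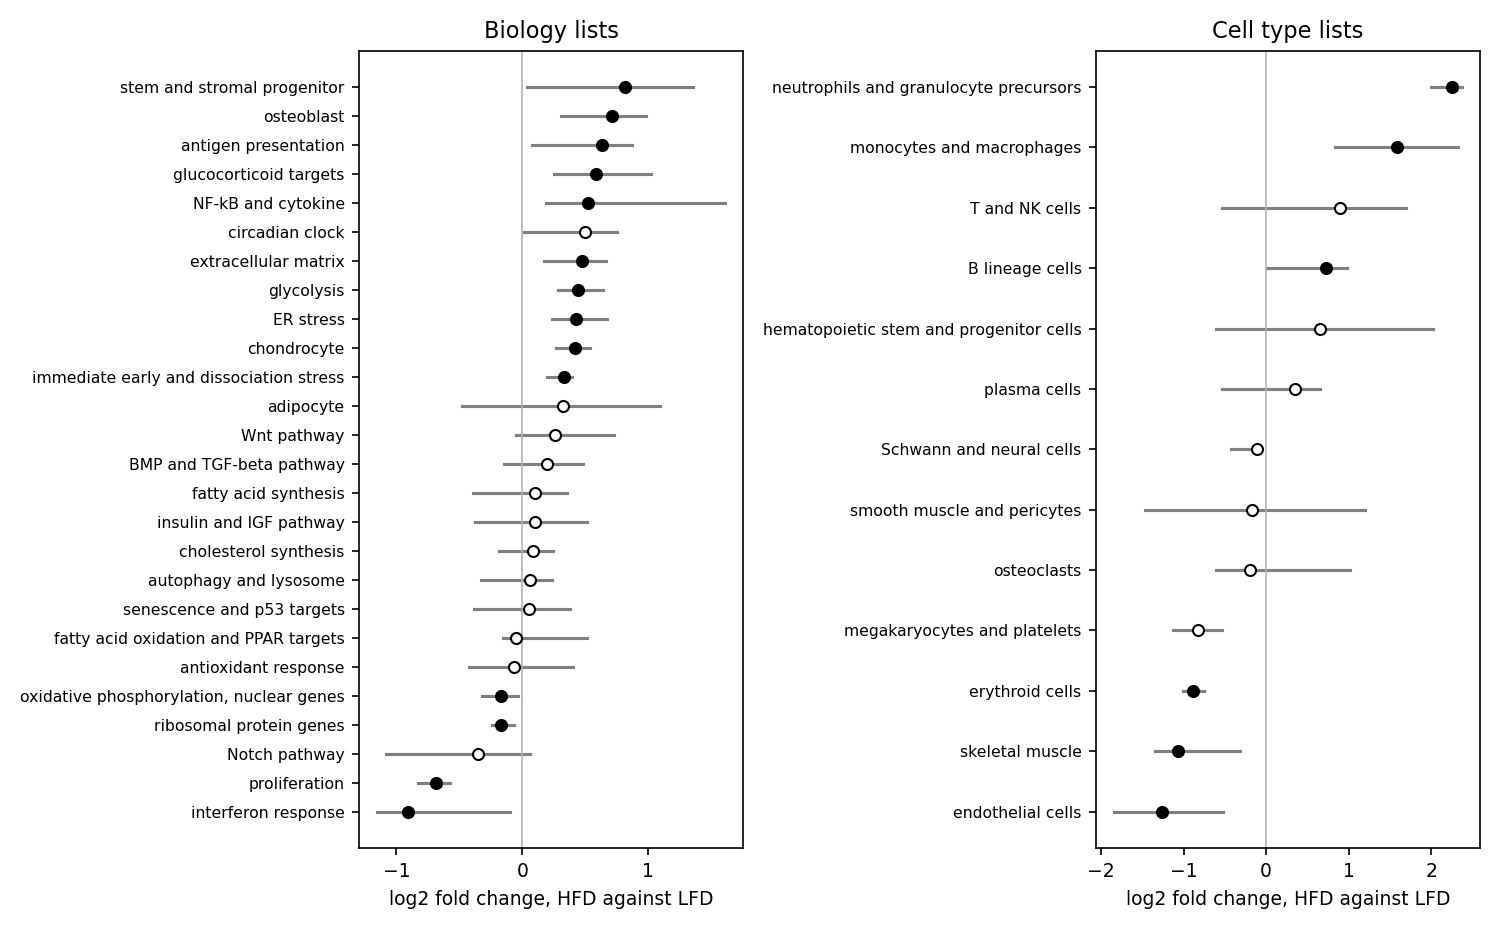
Median log2 fold change, HFD against LFD, of each tested list, with bars from the 25th to the 75th percentile of its members. Filled points are the 14 of 26 biology lists and 6 of 13 cell type lists with a camera adjusted p under 0.05 at a preset correlation, and 0 lists passed with an estimated correlation.

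Markers of myeloid cells were higher in HFD. All 21 genes of the neutrophil and granulocyte precursor list were higher, with a median log2 fold change of 2.24, 14 at an unadjusted p under 0.05, 13 passing when adjusted over the list alone, 0 over all genes tested and 11 called by DESeq2. S100a8 measured 534 ± 411 CPM in LFD and 2765 ± 884 CPM in HFD, and Ngp 771 ± 506 and 3652 ± 1424 CPM. The list rose by camera (adjusted p = 1.69e-12, adjusted p = 0.317 with an estimated correlation). Of 17 monocyte and macrophage genes 16 were higher (median 1.59), with Lyz2 at 345 ± 256 and 1732 ± 240 CPM, and the list rose (adjusted p = 7.74e-07, adjusted p = 0.250 with an estimated correlation). Lyz2, Cd14 and Fcgr1 passed when adjusted over that list alone. The common leukocyte antigen gene Ptprc measured 10.1 ± 10.5 CPM in LFD and 52.4 ± 3.21 CPM in HFD (adjusted p = 0.672). Of 22 B lineage genes 16 were higher (median 0.72), and the list rose (adjusted p = 0.00299, adjusted p = 0.557 with an estimated correlation), while its most abundant members Ighm (-0.78) and Igkc (-3.31) had negative values that turned positive without LFD 4. The B lineage call ended without LFD 1 (adjusted p = 0.153).

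Markers of red cells, muscle and vessels were lower in HFD. All 21 erythroid genes were lower (median -0.89), with 0 at an unadjusted p under 0.05. The erythroid list fell by camera (adjusted p = 9.51e-08, adjusted p = 0.557 with an estimated correlation of 0.956). Of 12 skeletal muscle genes 9 were lower (median -1.06), with Myf5, a factor of muscle progenitors, at 83.5 ± 20.6 CPM in LFD and 37.1 ± 1.81 CPM in HFD and Des at 165 ± 72.3 and 74.8 ± 1.30 CPM. Myf5, Des and Myod1 passed when adjusted over the list alone, and the list fell (adjusted p = 0.00853, adjusted p = 0.250 with an estimated correlation). Of 8 endothelial genes, all of low abundance, 7 were lower (median -1.26), and the list fell (adjusted p = 0.0382, adjusted p = 0.250 with an estimated correlation), a call that ended in 5 of 7 fits with a library left out, those without LFD 2, LFD 3, LFD 4, HFD 2 or HFD 4 (adjusted p = 0.0898, 0.104, 0.0567, 0.124 and 0.0540). The 7 other tested lists did not pass. Their median log2 fold changes were 0.66 for blood stem and progenitor cells (8 of 14 higher, adjusted p = 0.119), -0.17 for smooth muscle and pericytes (5 of 10, adjusted p = 0.217), -0.83 for megakaryocytes (2 of 9, adjusted p = 0.217), -0.11 for Schwann and neural cells (2 of 9, adjusted p = 0.236), 0.35 for plasma cells (3 of 5, adjusted p = 0.371), 0.90 for T and NK cells (3 of 5, adjusted p = 0.632) and -0.19 for osteoclasts (4 of 9, adjusted p = 0.939). The means of the smooth muscle (0.01) and osteoclast (0.32) lists had the other sign. Of the smooth muscle genes 5 passed when adjusted over the list alone (Des, Tagln, Acta2 and Notch3 lower, Abcc9 higher), as did Ctsk and Tcirg1 of the osteoclast list, genes chosen after their values were seen. Single libraries made calls of the blood progenitor list (without LFD 3 or LFD 4, adjusted p = 0.0374 and 0.0213), the Schwann list (without HFD 2, 0.0147) and the megakaryocyte list (without HFD 3, 0.0324). With 1 surrogate variable the erythroid (median 0.01, adjusted p = 0.431) and endothelial (-1.53, adjusted p = 0.0685) calls ended, and the smooth muscle list was newly called lower (-0.49, adjusted p = 0.0218). With the erythroid share in the model, chosen after seeing the data, the smooth muscle (-0.28, adjusted p = 0.0266) and Schwann (-0.57, adjusted p = 0.00835) lists were newly called lower.

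As a share of all counts, hemoglobin transcripts took 9.67% ± 0.94 in LFD and 5.49% ± 3.20 in HFD (exact permutation test, two-sided, p = 0.0286, the smallest of 35 assignments). The hemoglobin set, part of the erythroid list, was not among the lists fixed beforehand and stayed outside the adjustment. The erythroid list took 14.3% ± 2.45 and 8.15% ± 4.69 (exact permutation p = 0.0571) and ranged from 3.11% in HFD 2 to 17.1% in LFD 3. The diets overlapped for this list, with 12.4% in HFD 4 and 11.5% in LFD 1. The granulocyte list took 0.294% ± 0.226 in LFD and 1.497% ± 0.351 in HFD (exact permutation p = 0.0571), and the monocyte list 0.0755% ± 0.0286 and 0.252% ± 0.000791 (exact permutation p = 0.0286). The mast cell list (0.00145% and 0.0103%) and the dendritic cell list (0.00418% and 0.00560%), which had fewer than 5 tested genes each, were also at exact permutation p = 0.0286. Of 15 lists 3 had p under 0.05 and 0 passed after adjustment (smallest adjusted p = 0.122). The skeletal muscle list took 0.0360% ± 0.0133 and 0.0185% ± 0.000846 (exact permutation p = 0.0571).

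The transcripts of the sorting antigens did not pass. Cd24a measured 3471 ± 1448 CPM in LFD and 2077 ± 1161 CPM in HFD (log2 fold change -0.74 ± 0.56, adjusted p = 0.739), and Itgb1 426 ± 57.8 and 446 ± 59.8 CPM (0.07 ± 0.22, adjusted p = 0.952). Across the 7 libraries Cd24a followed the erythroid share (Pearson r = 0.911, exact permutation p = 0.00694, adjusted p = 0.0163 over 6 relations, Spearman rho = 0.964, exact permutation p = 0.00278), as did the mean of the proliferation genes (r = 0.888, exact permutation p = 0.00813, rho = 0.964). Without HFD 2 and HFD 3, the libraries farthest from the median share on the log2 scale, r was 0.899 for Cd24a and 0.860 for proliferation. Without HFD 2 and LFD 3, the farthest in percent, r was 0.612 and 0.625, so the strength of both relations rested in part on these libraries. Within the diets, with both measures centred on the mean of their diet and libraries permuted inside it (a test chosen after seeing the data), r was 0.898 for Cd24a and 0.875 for proliferation (exact permutation p = 0.00694 and adjusted p = 0.0208 for each). Both stood in the same order as the erythroid share in either diet. The osteoblast genes (r = -0.58, exact permutation p = 0.177, rho = -0.39, exact permutation p = 0.396) and the granulocyte genes (r = -0.42, exact permutation p = 0.362, rho = -0.39, exact permutation p = 0.396) did not follow it by these tests. For the osteoblast genes r was 0.729 without HFD 2 and HFD 3 and -0.49 without HFD 2 and LFD 3. Itgb1 was left undecided, with r = -0.49 (exact permutation p = 0.259), -0.70 and -0.71 without the former and the latter libraries, rho = -0.79 (exact permutation p = 0.0480, adjusted p = 0.0720), and r = -0.49 within the diets (exact permutation p = 0.382).

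**Figure D4:**
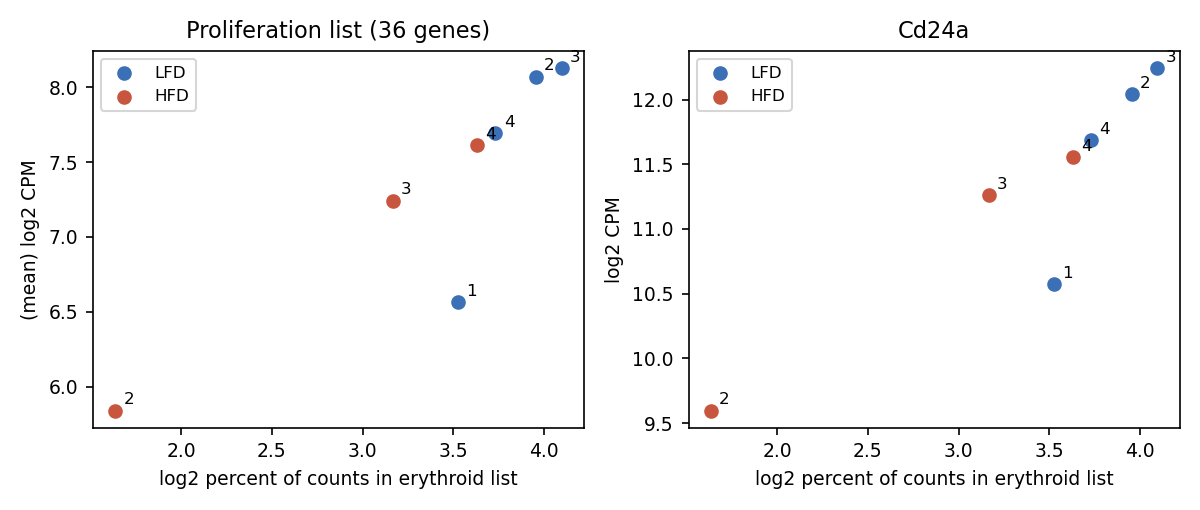
Mean log2 CPM of the 36 proliferation genes and log2 CPM of Cd24a against the log2 percent of counts in the erythroid list, with 1 point per library, its replicate number beside it, LFD in blue and HFD in red. Pearson r over the 7 libraries was 0.888 for proliferation and 0.911 for Cd24a.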

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

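The tests on sex, chromosomes, scaling, single libraries and erythroid share in this part, and the counts of splits by edgeR, by list and at unadjusted p, were chosen after the results they bear on had been seen. The count of DESeq2 splits was set beforehand, and the neutrophil genes outside the lists were chosen before their values were seen, after those of the granulocyte list.

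Sex and diet cannot be told apart for any gene, since 0 libraries had the sex-linked transcripts of the other diet group. Location on the X chromosome cannot account for most genes with unadjusted p under 0.05. Of those with a known position, 41 lay on X and 1033 elsewhere. Whether X genes were more often among them is left open. The shares were 8.63% of X genes and 7.49% of other genes (Fisher's exact p = 0.331, odds ratio 1.17 with 95% interval 0.821 to 1.62). For the edgeR count, 1 of 35 splits (the real split, with 5 genes) reached it and the highest other split gave 0, but the sex-linked genes fix this outcome and without them each split gave 0, so whether chance gave the rest was not decided. For unadjusted p under 0.05 chance is not excluded, since 5 of 35 splits gave as many genes (1077 in the real split, 2391 in the highest other). A mix-up of samples and an experiment with female LFD and male HFD mice both remain open and were not tested.

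The neutrophil and monocyte genes were higher in HFD, and C5ar1, an autosomal gene, is expressed by the same cells. The edgeR test called C5ar1 only with the sex-linked genes in the adjustment (adjusted p = 0.138 without them). DESeq2 (adjusted p = 1.12e-14) and limma-voom (adjusted p = 0.0222) called it too, with those genes in the adjustment. For the granulocyte list a single library was argued against, since its lowest median with 1 library left out was 1.96. For scaling the test on that list was not decided, since its criterion also asked for an exact permutation p under 0.05. The gap between the list and all tested genes within a library was larger in HFD by 2.88 ± 0.93 (log2, ± standard error). No factor per library can change that gap. Its exact permutation p was 0.0571, so a chance split of the libraries is not excluded for it. A larger share of myeloid cells among the sorted HFD cells is a candidate explanation that was not decided, as 18 of 18 neutrophil genes outside the lists were higher (median 2.36), but their mean did not pass (exact permutation p = 0.0571). S100a8 (2765 CPM in HFD) and Ngp (3652 CPM) were abundant, and the protocol names CD24 and CD29 and no step that removes blood cells. A change within the sorted stem cells, sex and diet stay open, and chance is not excluded for the number of cell type lists, where 7 of 35 splits gave as many (6 lists in the real split, 7 in the highest other).

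The lower proliferation genes and Cd24a in HFD may reflect the share of erythroid cells in the sort, since both followed that share with r = 0.888 and r = 0.911 over the 7 libraries (0.625 and 0.612 without HFD 2 and LFD 3). With the erythroid share in the model the proliferation median was 0.23, but it ranged from -0.09 without LFD 1 to 0.59 without HFD 2, which leaves open whether proliferation differed apart from that share. DESeq2 called 361 genes for the diets, yet 4 of 35 splits gave as many, so chance is not excluded for that count. The split with the highest count (1355) set LFD 1, HFD 2 and HFD 3 apart and the next (951) LFD 2, LFD 3 and LFD 4, which are the 3 libraries with the lowest and the 3 with the highest erythroid shares and point to a structure of the samples. For the biology lists, 1 of 35 splits reached the 14 lists of the real split, and the highest other gave 12.

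Of 126 values tested among the LFD libraries 4 had a library far from the other 3, where chance gives about 6. The Schwann and neural share was 0.0927% in LFD 1, where the others were at 0.0574% to 0.0602%. Agt was 36.0 CPM in LFD 2, where the others were at 26.3 to 27.5 CPM. Col5a2 was 508 CPM in LFD 3, where the others were at 354 to 366 CPM. Kitl was 0.498 CPM in LFD 3, where the others were at 3.70 to 4.30 CPM.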

How the results depend on the processing

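The erythroid share as a covariate, the removal of erythroid and granulocyte genes before normalization, and the adjustment without sex-linked genes were chosen after seeing the data. So was the fit of the 6 libraries with numbers 2 to 4 without a block, which equals the planned fit without LFD 1. With log2 fold changes of 1 mostly missed in simulation, absence of a call says little about changes of that size. Sex and diet coincide under every alternative. A test of 3 libraries against 3, or of 4 against 2, cannot reach p under 0.05 for shares of counts, so shares with a library left out say nothing about stability. With the erythroid share in the model the erythroid list had a median of 0.19 (adjusted p = 0.378), which is not counted as a change since that share is made from the same genes. Every alternative was run except the denominator without mitochondrial genes, which are not analysed here. The cause of the changes below was not tested unless given.

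With RLE and upper-quartile scaling and without robust fitting the same 5 genes were called by edgeR, as they were after erythroid and granulocyte genes had been removed. Under all alternatives, 2073 values for named genes kept their direction and side of the threshold. A further 54 passed it newly, 12 lost it and 14 changed sign. For gene lists these counts were 517, 17, 75 and 47. Among the named genes C5ar1 alone passed in the main test, and all 12 losses were its own. It passed in 8 of its 20 alternatives. The 2073 values were nearly all of genes that did not pass in either fit, so they do not show that calls were stable. With an estimated correlation 0 biology lists and 0 cell type lists were called, and with fry 0 and 0.

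DESeq2 called 361 genes (285 higher, 76 lower) and limma-voom 28 (25 and 3), where the 5 edgeR genes were among both. With limma-voom the log2 fold change was -0.0685 for Col2a1 and 0.34 for Tek. An adjusted p under 0.1 gave 10 genes (8 higher, 2 lower). Without a low count filter edgeR called 8 genes (7 higher), and list medians were -0.00302 for insulin, 0.78 for osteoclasts, -0.51 for plasma cells and 0.37 for smooth muscle, since more members were tested. The stricter filter gave 0 genes (0 higher, 0 lower, 988 at an unadjusted p under 0.05), by construction for the Y-linked genes, which 3 libraries expressed, but not for Xist. With the sex-linked genes left out of the adjustment 0 genes were called (0 higher, 0 lower, 1072 at an unadjusted p under 0.05), because the remaining genes lost the higher ranks.

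With replicate number as a block on the libraries numbered 2 to 4, edgeR called 0 genes (0 higher, 0 lower, 1342 at an unadjusted p under 0.05), and the medians were 0.33 for fatty acid oxidation and 0.29 for smooth muscle. The same libraries without the block gave 3 genes (0 lower), with medians of 0.10 and 0.19. Nothing in the labels says that the numbers pair the libraries.

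With 1 surrogate variable 2 genes were called (2 higher, 0 lower). Medians became 0.0650 for antioxidant genes, -0.23 for cholesterol synthesis, 0.0144 for erythroid cells, 0.0686 for fatty acid oxidation, -0.25 for fatty acid synthesis, 0.0845 for interferon response, 0.22 for osteoclasts, 0.16 for proliferation and -0.0538 for p53 targets, and log2 fold changes 0.0255 for Aurkb, 0.17 for Cd24a and -0.12 for Itgb1. With the erythroid share in the model 1 gene was called (1 higher, 0 lower) and 7 biology lists. Medians became 0.12 for antioxidant genes, -0.16 for cholesterol synthesis, 0.11 for fatty acid oxidation, -0.33 for fatty acid synthesis, 0.33 for megakaryocytes, 0.41 for osteoclasts, -0.0373 for plasma cells, 0.23 for proliferation, -0.0614 for p53 targets and -0.25 for Wnt genes, and log2 fold changes 0.0278 for Ccnb2, 0.27 for Cd24a, -0.0728 for Itgb1, 0.0476 for Rrm2 and 0.0808 for Tyms.

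With each library left out in turn, edgeR called 1 to 6 genes, 1 to 6 of them higher and 0 to 1 lower, with 1 gene (Ddx3y) without LFD 2, HFD 2, HFD 3 or HFD 4, 3 without LFD 1 and 6 without LFD 4. Medians ranged from -0.56 to 0.0192 for Notch, -0.47 to 0.0458 for Schwann cells, -0.0446 to 0.19 for cholesterol synthesis, -0.12 to 0.10 for fatty acid oxidation, -0.14 to 0.27 for fatty acid synthesis, -0.0330 to 0.28 for insulin, -0.39 to 0.11 for osteoclasts, -1.61 to 0.39 for plasma cells, -0.19 to 0.31 for p53 targets and -0.30 to 0.22 for smooth muscle. Log2 fold changes ranged from -1.16 to 0.99 for Ighm, -4.42 to 0.36 for Igkc, -0.00428 to 0.17 for Itgb1 and -1.12 to 0.54 for Pecam1, and the B lineage share from -0.30 to 1.06.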

Other observations

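The tests in this part were chosen after the Lepr, Cxcl12 and Myf5 values had been seen in the same libraries, on genes whose own values had not been seen.

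Genes of marrow reticular stromal cells outside the lists used above were higher in HFD. All 9 tested (Gas6, Kng1, Kng2, Esm1, Il7, Angpt1, Cxcl14, Rarres2 and Serping1) had positive values, with a median log2 fold change of 1.11. Their mean log2 CPM was 2.88 ± 0.91 in LFD and 4.67 ± 0.58 in HFD (exact permutation p = 0.0286, the smallest that 35 splits can give). That p was not adjusted for the other tests on genes outside the lists. Lepr and Cxcl12 already separated the same libraries, so it is not independent support. Gas6, a ligand of TAM receptors, measured 101 ± 24.0 CPM in LFD and 230.1 ± 38.8 CPM in HFD, Esm1 3.64 ± 3.62 and 23.9 ± 5.94 CPM, and Kng1 1.05 ± 1.17 and 16.2 ± 4.02 CPM, while the log2 fold changes of Serping1 (0.04) and Rarres2 (0.11) were near 0. None passed edgeR's threshold over all genes (smallest adjusted p = 0.254, 3 at an unadjusted p under 0.05), and DESeq2 called Gas6 and Kng1 (adjusted p = 0.00359 and 0.0430). The hypothesis that more reticular stromal cells were among the sorted HFD cells could account for these values, but sex, diet and the erythroid share, which the related progenitor list followed, remain open.

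The hypothesis that fewer muscle satellite-like cells were among the sorted HFD cells was not borne out by genes outside the muscle list, and not excluded. Of 7 tested genes 4 were lower, with a median log2 fold change of -0.33, and their mean log2 CPM was 6.16 ± 0.44 in LFD and 5.93 ± 0.15 in HFD (exact permutation p = 0.486). Megf10 (-0.89) and Cdh15 (-1.04) were lower at an unadjusted p under 0.05, 0 passed edgeR's threshold over all genes (smallest adjusted p = 0.266), and DESeq2 called Megf10 (adjusted p = 0.00150). Sdc4 (0.34), Chrdl2 (0.19) and Msc (0.08) had positive values.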
